A study of Mus musculus with 4 samples.

How the data were processed

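Total RNA of 4 mouse neural progenitor cell samples was measured, 2 controls and 2 transduced with a retrovirus carrying OVOL2. Per the labels' protocols, the RNA was prepared with RNeasy columns, labelled with biotin by the standard Affymetrix procedure, and the cells were grown in a serum-free medium with B27, a ROCK inhibitor, epidermal growth factor and epigallocatechin gallate. Groups were taken from the transduction field of the labels. Other samples of the wider study, from human tissue or other transductions, were not analysed here.

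The deposited table holds 1 log2 value per probe set and array, and the scale is read from the values, which run from 4.20 to 13.40. How the authors corrected the background, normalised the arrays and summarised the probes is not given in the sources used here. The medians and upper quartiles of the arrays are close but the distributions are not identical, and no centring per gene is seen. Arrays brought to a like scale cannot show a shift of all transcripts in one direction. The table gives no detection calls, so a low value cannot be told from background, and no filter on dim genes was used in the main test.

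Of 33793 probe sets, 23521 had 1 gene symbol, 1820 had several and 8452 were not listed with a gene, in a platform annotation that can be old. Symbols were looked up by Entrez number in a RefSeq gene table of assembly GRCm38.p6, used for names only. Of the probe sets with 1 symbol 23328 matched and 0 symbols changed. Probe sets with several symbols name no gene here, so some members of the lists were not measured. Where a gene had more than 1 probe set (1082 genes), the one with the highest mean over the 4 arrays was used, which left 22180 genes. Array control probes for RNA quality were not in the table used here, so the planned comparison of 3' and 5' control probes was not run.

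Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the log2 values, two-sided, with no covariate, 2 residual and 2.63 prior degrees of freedom, and a Benjamini-Hochberg adjusted p under 0.05. Folds are 2 to the power of the log2 difference, and array folds tend to be compressed for dim and for very bright probe sets. The 32 gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, for lists with at least 5 measured genes. Camera with a correlation estimated from the arrays, which rests on the 2 residual degrees of freedom, and fry were run beside it. Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Ovol2, the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap, and from each list up to 2 rises and 2 falls, or up to 5 each way in the epithelial, EMT, mesenchymal and neural progenitor lists. It named 131 genes, of which part is given in the text, and genes from outside it are marked where they appear.

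The test was tested on simulated data made from the real means and the fitted spread of the 22180 genes, with independent genes, with 200 genes changed in each of 5 simulations of this comparison. It recovered 0.8% of the genes changed by 0.5 log2 units, 64% of those changed by 1, 96.4% of those changed by 2 and 99.2% of those changed by 4, with 5 false calls on average and 0 calls when no gene was changed. Camera called 5 of 5 planted lists and 1 of 5 random lists at an unadjusted p of 0.05. The planted lists held only raised genes, and the check was set to stop unless all 5 were called. With independent genes these list counts do not give camera's error for lists whose genes move together. The recovered shares of genes hold for 200 changed genes, and with more genes changed the adjusted threshold is less strict. The simulation also gave both groups of a gene the same spread. In the data the pair labelled OVOL2 differed more than the control pair (SD of the difference 0.251 against 0.138). The simulated false calls therefore do not give the rate for these arrays. Alternatives were quantile normalisation, median centring, a floor at the 20th percentile of all values, a filter at the 40th percentile of gene means, the mean of a gene's probe sets, every probe set on its own, an intensity trend or robust spread in eBayes, the replicate number as a block, other thresholds and leaving out each array in turn.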

Results

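The series measured total RNA from mouse neural progenitor cells (NPCs), cultured cells that can give rise to neurons and glia, on an Affymetrix whole-transcript expression array. There were 4 arrays, 2 from control NPCs and 2 from NPCs transduced with a retrovirus carrying OVOL2, a zinc finger transcription factor of epithelial tissues. The series title places the experiment in a study of transcription factors of the corneal epithelium, and the comparison asks which transcripts differ in NPCs given OVOL2. Neither the titles nor the transduction field say whether the controls received a virus without OVOL2. By these fields an effect of transduction itself cannot be told apart from one of OVOL2. Each array gave a value for 33793 probe sets, with medians between 5.56 and 5.61 and upper quartiles between 7.35 and 7.49 on the log2 scale. Over all probe sets the control arrays correlated at r = 0.997 and the arrays labelled OVOL2 at r = 0.987, both across probe sets, which are not independent replicates. Between groups r lay between 0.954 and 0.971. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision: an exact permutation test of 2 against 2 cannot go below p = 0.333, and the tests below use limma's spread pooled over genes.

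The transduced factor was examined first. The table held 1 probe set for Ovol2 (probe set 17392403), and it was not higher on the arrays labelled OVOL2. Its values were 6.17 and 6.03 on the control arrays and 6.21 and 6.09 on the arrays labelled OVOL2. The log2 difference was 0.05 (SE 0.09, 95% interval -0.19 to 0.28), with a limma adjusted p of 0.792. The labels give neither the species nor the part of OVOL2 that the virus carried, so the probe set checks the labels only if it matches the transgene. Every direction below is therefore drawn between the arrays labelled OVOL2 and the arrays labelled control.

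Many transcripts differed between the groups. Of 22180 genes tested, 5196 passed an adjusted p of 0.05 in limma, with 2471 higher and 2725 lower on the arrays labelled OVOL2. At least a 2-fold difference was found for 1364 of them, 546 higher and 818 lower. The arrays of the groups did not overlap for 60.7% of all genes, where chance gives 33.3% on average. Genes on the same arrays are not independent, so the share of this split can differ from that average without an effect. Without either control array no gene passed the adjusted threshold in limma (0 genes, against 5081 and 4996 genes at an unadjusted p under 0.05). Without array 1 labelled OVOL2 the count of lower genes was 4304. With low values set to a floor 2847 genes passed, and 53 of the 131 named genes no longer did. Of the genes described below these were Dynap, Osmr, Dcn, Col6a2, Boc, Fgfr2, Hbegf, Fas, Perp, Cdkn1a, Grem1, Fst, Lif, Epcam, Cldn6, Pkp1, Dsp, Mpp5, Tjp1, Spint1, Lad1, Clu, Prrx1, Sim2, Foxc1, Foxf2, Snai2, Etv4, Sox21, Slc1a3, Gli2, Sox4 and Msi1. Prrx1 and Snai2, with no value under 10.24, lie far above the floor, so their loss came from the pooled spread or the adjustment. Counts with the floor given below share this limit and do not by themselves show dim signal. With every probe set tested on its own 18 named genes lost their call, of those below Grem1, Cdkn1a, Dsp, Pkp1, Lad1, Tjp1, Sim2 and Lif. The counts of the lists below moved by over 1.5 times in at least 1 direction for 25 of the 32 lists with the floor, and for 13 each without array 1 or array 2 labelled OVOL2. These are given with each list, and without either control array they were 0.

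For 14 named genes the mean of a group lay below 5.56, the lowest array median, where a value cannot be told from background. Their differences are lower bounds in size, and their order among the named genes is not defined. They include Akr1c18, Nefl, Dynap, Tigit, Cavin4, Wnt7b, Saa3, Postn, Epcam, Erbb3 and Hhip, and Cldn6, with both means below, is given no size. Akr1c18, a steroid dehydrogenase of the aldo-keto reductase family, rose from 5.55 ± 0.10 to 10.78 ± 0.32 (mean log2 value ± SD, n = 2 arrays). Probe sets of this family can share sequence, so its identity is less certain. Nefl, the light chain of neurofilaments, was at least 4.86 log2 units higher (SE 0.29) and Dynap at least 4.70 (SE 0.53, with 5.50 without array 1 labelled OVOL2 and 3.90 without array 2). Aldh3a1, an aldehyde dehydrogenase abundant in the cornea, rose 10.3-fold from 7.93 to 11.30, and Cldn9, a tight junction claudin, rose 10.0-fold. Itgb7 rose by 3.38 log2 units and Mfsd2a, a lysophospholipid transporter, by 3.35, while Tigit, Cavin4 and the signalling ligand Wnt7b rose by at least 3.08, 3.03 and 2.97. Limma adjusted p-values of these 10 genes lay between 0.000999 and 0.00623.

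Among the 10 genes with the largest measured falls were inflammation and matrix genes. Saa3, an acute phase protein, fell at least 40.2-fold, from 10.49 ± 0.01 to 5.16 ± 0.17 (SD, n = 2 arrays), and Lcn2, lipocalin 2, fell 28.2-fold. Osmr, the receptor subunit for oncostatin M, changed by -4.48 log2 units (SE 0.42), with -5.12 without array 1 labelled OVOL2 and -3.85 without array 2. The matrix genes Postn (periostin), Col12a1 (a collagen chain) and Prelp (a leucine-rich proteoglycan) changed by -4.28 (a lower bound in size), -3.90 and -3.81, and a further probe set of Prelp gave -0.45. Islr, Cpxm1, Steap4 and Rspo2 (an R-spondin that amplifies WNT signalling) changed by between -4.11 and -3.81. Limma adjusted p-values lay between 0.000849 and 0.00422.

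**Figure D1:**
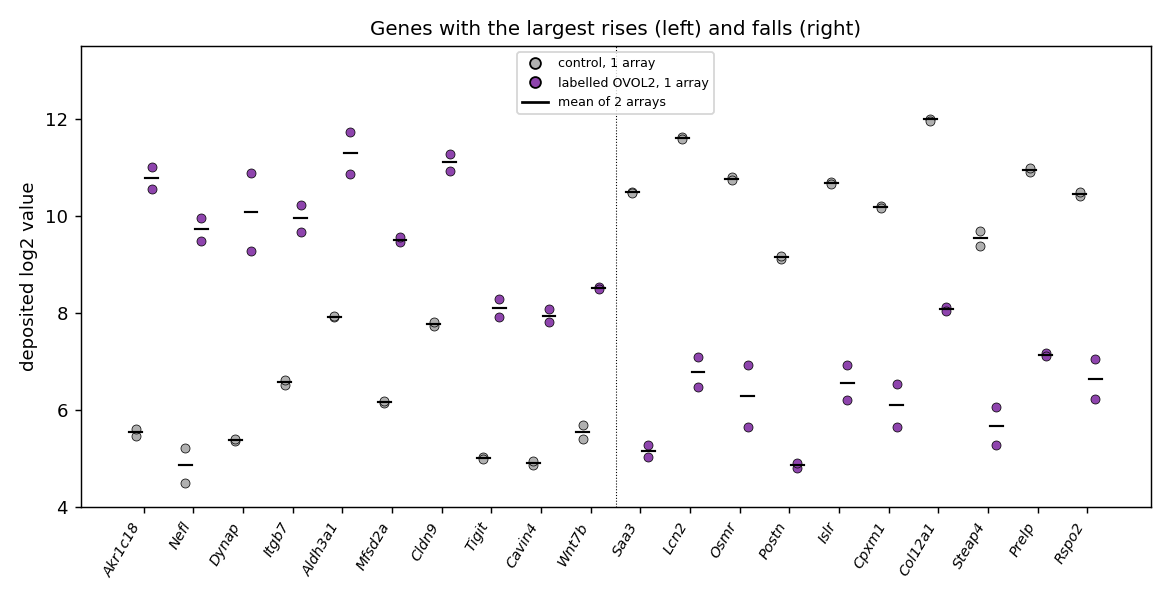
Deposited log2 values (vertical axis) of the 10 genes with the largest measured rises and the 10 with the largest measured falls, with 1 point per array, grey for control and purple for arrays labelled OVOL2, and bars at the mean of 2 arrays. For Saa3 the control mean is 10.49 and the other mean 5.16, and for Akr1c18 they are 5.55 and 10.78.

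Of 49 measured genes of mesenchymal matrix and adhesion, 31 fell, 6 rose and 12 did not pass the test, with a median difference of -1.07 (32 lower and 7 higher when adjusted over the list alone, 21 and 2 with the floor). In the controls 42 of the 49 lay above the upper quartile, as did 14 of 21 genes of fibroblasts and meninges. Of 45 neural stem and progenitor genes 12 did. The control samples thus held strong mesenchymal signal, and which cells made it was not tested. Col1a1, the main chain of fibrillar type I collagen, fell from 11.68 ± 0.02 to 8.45 ± 0.12 (SD, n = 2 arrays). Dcn (decorin) changed by -3.20 (SE 0.52, with -3.98 without array 1 labelled OVOL2 and -2.42 without array 2), Acta2, the smooth muscle actin, by -2.41 and Col6a2 by -2.37. S100a4, a calcium-binding protein of motile cells, rose 3.78-fold, and Cav1, the caveolae protein, 2.19-fold. The camera test of limma gave the list an adjusted p of 3.16e-08 over the 32 lists, and with an estimated correlation the adjusted p = 0.321. In the list of fibroblasts and meninges 14 of 21 genes fell and 1 rose, with a median of -1.38 (15 lower and 1 higher when adjusted over the list alone, 7 and 1 with the floor, 15 and 2 without array 2 labelled OVOL2). Fmod (fibromodulin) changed by -3.37, with -1.98 on its further probe set, and Crabp2, a retinoic acid binding protein, rose by 1.60 log2 units. Camera gave an adjusted p of 3.63e-07, and adjusted p = 0.321 with an estimated correlation. The lists share 6 genes, and the 43 other mesenchymal genes held 25 that fell and 6 that rose (camera adjusted p = 4.59e-06, and 0.337 with an estimated correlation, tests chosen after seeing the data).

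Of 21 measured EMT transcription factors, regulators of the transition from epithelial to mesenchymal cells, 9 fell, 2 rose and 10 did not pass (11 lower and 3 higher when adjusted over the list alone, 1 and 1 with the floor). Prrx1 changed by -0.90 (SE 0.12), Sim2 by -0.89, Foxc1 by -0.79, Foxf2 by -0.63 and Snai2, a repressor of E-cadherin, by -0.64 (SE 0.11). Hmga2 and Etv4 rose by 0.62 and 0.76. Zeb1, chosen after its values were seen, fell from 7.27 to 6.71. The list's camera adjusted p was 0.0617, and 0.672 with an estimated correlation. It was 0.0355 without array 1 labelled OVOL2 and 0.0328 with the mean of each gene's probe sets.

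Genes of epithelial junctions and polarity went both ways, with 10 of 38 higher, 3 lower and 25 not past the threshold, a median of 0.08, and the same counts when adjusted over the list alone. The floor left 1 higher and 1 lower, and without array 1 labelled OVOL2 there were 10 and 5. Epcam, an epithelial adhesion molecule, rose at least 2.17-fold to 6.16 ± 0.36 (SD, n = 2 arrays), and the desmosome gene Pkp1 rose 1.71-fold, while Dsp (desmoplakin) went from 6.03 to 7.03. Ppl rose by 0.65 log2 units. Cxadr, Mpp5 and Tjp1, junction and polarity proteins, changed by -0.78, -0.60 and -0.35. Cdh1, E-cadherin, chosen after its values were seen, had means of 5.93 in the controls and 6.52 on the arrays labelled OVOL2. With the floor Ppl was the 1 junction gene still higher, so Cdh1 was not called there. The camera adjusted p was 0.144, and 0.453 with an estimated correlation, while fry, which asks whether a list's genes move one way on balance, gave 0.0156. Among 37 epithelial regulators and proteases 5 rose and 3 fell, with a median of 0.00 and the same counts when adjusted over the list alone, 3 and 4 with the floor and 7 and 6 without array 1 labelled OVOL2. Klf5, a transcription factor of proliferating epithelia, rose 3.28-fold (SE 0.07 log2). Spint1, an inhibitor of membrane serine proteases, rose 2.57-fold, Cd24a 2.14-fold, Lad1 1.87-fold and Erbb3 at least 1.32-fold. Trp63, a regulator of stratified epithelia, changed by -0.80, Rab20 by -0.59 (-0.07 on its further probe set) and Shroom3 by -0.52. Camera gave an adjusted p of 0.905, and 0.907 with an estimated correlation.

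Of 37 keratin and corneal epithelium genes 10 rose, 1 fell and 26 did not pass, with a median of 0.14 (11 higher and 1 lower when adjusted over the list alone, 4 and 0 with the floor). Krt18, a keratin of simple epithelia, rose 7.78-fold from 5.98 to 8.94, and its further probe set gave 1.31 log2 units. Aldh3a1, in this list, is described above. Clu (clusterin) changed by -0.94. The camera adjusted p was 0.00102, and adjusted p = 0.366 with an estimated correlation.

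Cell cycle genes rose together. All 35 measured genes of the G2 and M phases rose, with a median of 1.29 and differences from 0.65 to 1.94. Birc5 (survivin), of the chromosomal passenger complex, rose 3.84-fold and Nuf2, a kinetochore protein, 3.61-fold. Of 30 S phase genes 28 rose and none fell, with a median of 1.22. Rrm2, a subunit of ribonucleotide reductase, rose 5.49-fold, with 0.28 log2 units on its further probe set, and Cdc6, which licenses replication origins, rose 5.27-fold. These counts were the same when adjusted over the list alone. Camera adjusted p-values were 6.47e-25 and 4.59e-20, and with an estimated correlation the adjusted p = 0.321 for G2 and M and 0.337 for S phase.

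Metabolic genes that rose included 15 of 17 of cholesterol synthesis, with none lower and a median of 0.67 (16 higher and 1 lower when adjusted over the list alone). Mvk, mevalonate kinase, rose 2.82-fold and Lss, lanosterol synthase, 2.21-fold. Of 27 oxidative phosphorylation genes 10 rose and none fell (11 higher when adjusted over the list alone, 6 with the floor), with a median of 0.26, led by Cycs (cytochrome c), 4.70-fold higher with 0.72 to 2.56 log2 units on its further probe sets, and Cyc1, 1.85-fold. Camera adjusted p-values were 1.54e-08 and 5.88e-06, and with an estimated correlation the adjusted p was 0.366 and 0.321. Of 15 housekeeping controls 7 rose and 1 fell, with a median of 0.15 (7 higher and 2 lower when adjusted over the list alone, 4 and 1 with the floor, 6 and 2 without array 1 labelled OVOL2, 7 and 2 without array 2). Tfrc, the transferrin receptor, rose 5.61-fold, and B2m, which is also in the interferon list, changed by -0.64. The housekeeping list had a camera adjusted p of 0.0314, and 0.366 with an estimated correlation. It was lost without array 1 (0.0777) or array 2 (0.0529) labelled OVOL2, under quantile normalisation (0.0711) and under the filter on dim genes (0.107).

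Part of the interferon list and part of the inflammation list fell. Of 28 interferon response genes 17 fell and none rose, with a median of -0.81 (18 lower when adjusted over the list alone, 11 with the floor). Ifit1, an antiviral RNA-binding protein, fell 5.63-fold and Bst2 (tetherin) 4.32-fold. Of 24 genes of NF-kB and inflammation 8 fell, among them Saa3 and Lcn2, and Lif rose by 0.42 (12 lower and 2 higher when adjusted over the list alone, 4 and 0 with the floor, 11 and 3 without array 1 labelled OVOL2). The median of the 24 was -0.29. Camera adjusted p-values were 1.41e-08 and 0.00547, and with an estimated correlation the adjusted p was 0.321 and 0.337.

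In the TGF-beta and BMP pathway 16 of 32 genes fell and 2 rose, with a median of -0.49 (18 lower and 3 higher when adjusted over the list alone, 7 and 1 with the floor, 16 and 4 without array 2 labelled OVOL2). Bmp4, a secreted ligand, fell 4.08-fold, while Fst (follistatin) rose 2.40-fold and Id2 2.10-fold. Grem1, a BMP antagonist, changed by -1.91 (SE 0.46), with -2.60 without array 1 labelled OVOL2 and -1.22 without array 2. In the Hedgehog pathway 6 of 16 fell, the same number when adjusted over the list alone, and 1 with the floor. The median of the 16 was -0.11 and their mean -0.68, so a few large falls weighed on this list. Without array 2 labelled OVOL2 2 of these genes rose and 6 fell. Boc, a co-receptor, changed by -3.26, and Hhip, a Hedgehog-binding protein, fell by at least 3.03 log2 units. In FGF and EGF signalling 9 of 27 fell and 3 rose, with a median of -0.17 (11 lower and 4 higher when adjusted over the list alone, 5 and 0 with the floor). The receptors Fgfr2 and Egfr changed by -2.57 and -1.90, and the ligand Hbegf by 1.14. Camera adjusted p-values were 0.00067, 0.0193 and 0.0382, and with an estimated correlation the adjusted p was 0.47, 0.672 and 0.366. The FGF and EGF list was lost without array 2 of the controls (0.0642), without array 1 labelled OVOL2 (0.0747) and under the filter on dim genes (0.136). The Hedgehog list was lost without array 2 labelled OVOL2 (0.121) and with fry (0.108), and the TGF-beta list with fry (0.0515).

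The list of neural stem and progenitor cells was not called as shifted, with 2 of 45 genes higher, 7 lower, 36 not past the threshold and a median of -0.04, and the same counts when adjusted over the list alone. In the controls 16 of the 45 lay below the array median and 12 above the upper quartile. A fall of the dimmer genes may not be seen, so the lack of a call does not show that these genes were kept. Higher and lower genes numbered 1 and 2 with the floor, 4 and 13 without array 1 labelled OVOL2 and 7 and 8 without array 2. Sox21, a neural transcription factor, rose 2.07-fold, with 0.16 log2 units on its further probe set. Slc1a3, a glial glutamate transporter, changed by -1.64 (SE 0.25), Gli2 by -0.96, Sox4 by -0.91, the RNA-binding protein Msi1 by -0.71 and Notch1 by -0.59. Sox2, chosen after its values were seen, had 8.89 ± 0.15 in the controls and 9.62 ± 0.34 on the arrays labelled OVOL2, with a limma adjusted p of 0.0548. The camera adjusted p was 0.45, and 0.856 with an estimated correlation. Of 28 astrocyte genes 12 fell and 2 rose, with a median of -0.28 (14 and 3 when adjusted over the list alone, 5 and 1 with the floor, 11 and 1 without array 2 labelled OVOL2). Sparcl1, a matricellular protein of astrocytes, fell 13.3-fold and Agt (angiotensinogen) 6.33-fold, and Gja1 (connexin 43) rose 1.77-fold. That list had a camera adjusted p of 0.00884, and 0.492 with an estimated correlation.

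**Figure D2:**
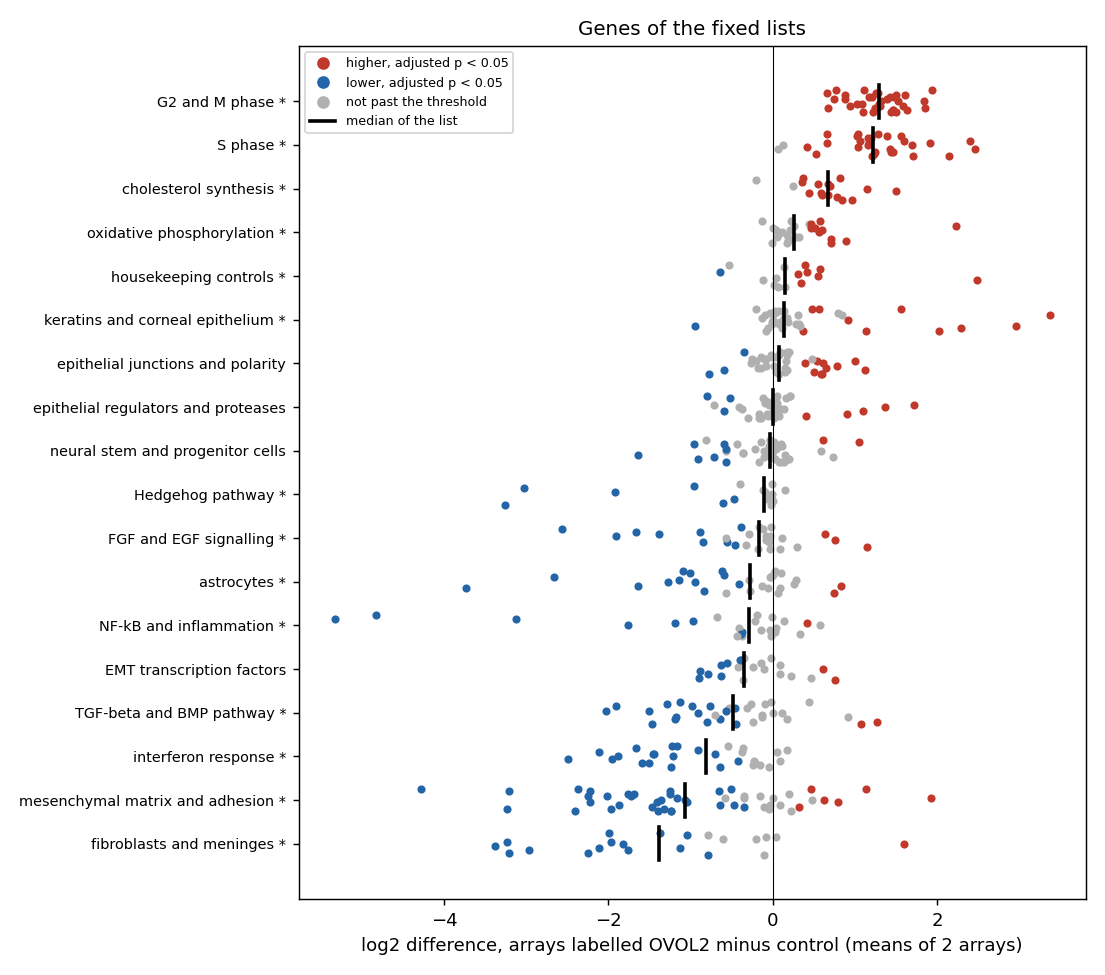
Log2 differences between arrays labelled OVOL2 and control (horizontal axis, means of 2 arrays) for the measured genes of 18 lists, 1 point per gene, red for higher, blue for lower and grey for genes not past the threshold, with a black bar at each list's median and an asterisk on lists with a camera adjusted p under 0.05. The G2 and M list lies wholly to the right, from 0.65 to 1.94, and the median of the fibroblast list is -1.38.

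Camera called no shift in the 14 remaining lists, all with an adjusted p of at least 0.186, while fry called endothelial and mural cells (adjusted p = 0.0159, down) and immediate early genes (adjusted p = 0.0314, up). Of 44 neuronal genes 3 rose, Nefl and Gad2 among them, and 2 fell, Map2 by -1.52 and Ncam1 by -0.64. Of 26 oligodendrocyte lineage genes 3 fell and none rose. Of 24 genes of endothelial and mural cells 5 fell, led by Notch3 at -1.92, and 1 rose. Of 19 microglia and blood cell genes none passed. Pluripotent cell genes had 1 higher and 2 lower of 17, neural crest and sensory placode genes 3 and 3 of 20, and choroid plexus and ependyma genes 1 and 1 of 15. Of 22 p53 target and apoptosis genes 5 rose, with Perp 4.88-fold and Cdkn1a 2.32-fold, and 2 fell, with Fas 6.19-fold. The unfolded protein response had 5 higher and 6 lower of 21, glycolysis and hypoxia 8 and 7 of 24, the Notch pathway 2 and 5 of 22, and the WNT pathway 4 and 8 of 28. In the WNT list Apcdd1 rose 5.25-fold and Sfrp1, a secreted WNT antagonist, fell 12.9-fold. Immediate early genes had 4 higher, with Jun 2.36-fold, and 1 lower of 19. Ribosomal protein genes had 6 higher and 2 lower of 35. When adjusted over the list alone, higher and lower genes numbered 6 and 5 for p53 targets, 7 and 6 for the unfolded protein response, 8 and 9 for glycolysis, 2 and 6 for Notch, 8 and 11 for WNT, 5 and 1 for immediate early genes and 2 and 2 for pluripotent cells, and the other 7 lists had the counts already given. With the floor they numbered 0 and 0 for p53 targets, 4 and 2 for the unfolded protein response, 6 and 4 for glycolysis, 1 and 3 for Notch, 4 and 3 for WNT, 2 and 0 for immediate early genes and 1 and 2 for ribosomal proteins. They were 0 and 5 for endothelial and mural cells, 1 and 0 for pluripotent cells and 2 and 1 for choroid plexus. Without array 1 labelled OVOL2 they were 6 and 6 for p53 targets, 6 and 4 for neurons, 5 and 5 for immediate early genes, 3 and 1 for pluripotent cells, 2 and 6 for neural crest, 2 and 4 for choroid plexus, 1 and 3 for oligodendrocytes and 0 and 1 for microglia. Without array 2 they were 6 and 4 for p53 targets, 6 and 3 for neurons, 7 and 5 for ribosomal proteins, 2 and 5 for endothelial cells, 2 and 1 for choroid plexus, 1 and 3 for oligodendrocytes and 1 and 1 for microglia. In several of these lists the median, the mean and the test differed in sign, among them the ribosomal proteins, with a median of -0.07 and a mean of 0.02.

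Both arrays labelled OVOL2 were set against the same control mean, so the list medians of array 1 and array 2 share its error and are not independent. The median of the G2 and M list was 1.35 on array 1 and 1.28 on array 2, that of the interferon list -0.72 and -0.98, and that of the mesenchymal list -0.96 and -1.17.

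**Figure D3:**
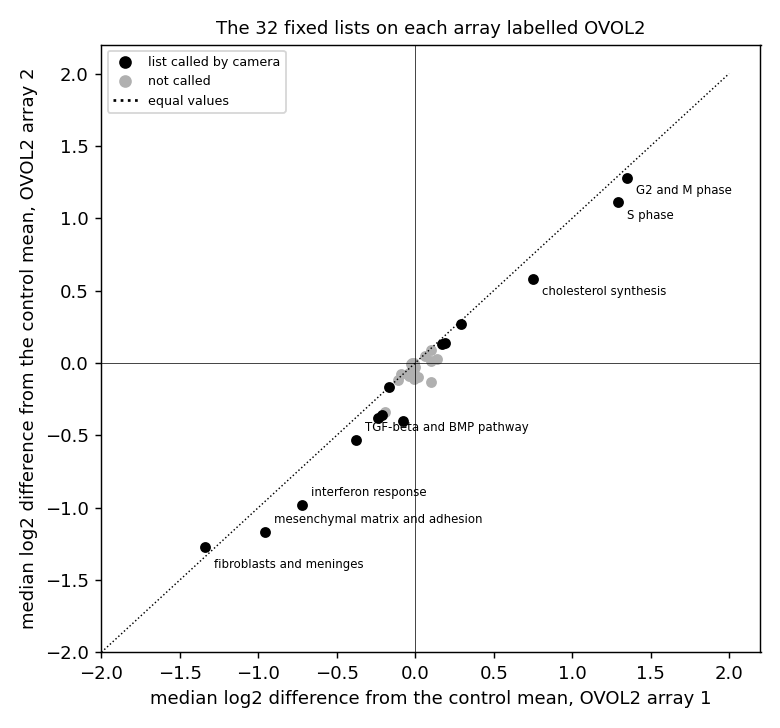
Median log2 difference from the control mean, shared by both axes, of each of the 32 lists on array 1 (horizontal axis) and array 2 (vertical axis) labelled OVOL2, 1 point per list, black where camera called the list, with a dotted line at equal values. The interferon list lies at -0.72 and -0.98 and the G2 and M list at 1.35 and 1.28.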

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

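The Ovol2 difference, the count of changed genes and the test of every probe set on its own were planned, and their use below to weigh explanations was chosen after the results were seen. Probe sets outside the gene tests also differed between the groups, both ways and in smaller shares than the genes. Of 8452 probe sets not listed with a gene, 232 were higher on the arrays labelled OVOL2 and 230 lower in limma. Each probe set was tested on its own here, and 5.5% of this class passed, against 23.4% of genes in the main test. The largest rise among these probe sets was 2.70 log2 units, on probe set 17356425, and the largest fall -4.72, on probe set 17346528. Of 1820 probe sets with several gene symbols, 172 were higher and 121 lower, 16.1% of that class.

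The probe set of Ovol2 was not higher on the arrays labelled OVOL2. Arrays that did not differ from the controls are argued against by the 23.4% of genes tested that passed the threshold. That share does not tell OVOL2 from any other difference between the pairs, so it does not check the labels. Whether the probe set sees the transgene stays open. The upper bound of the 95% interval of the difference, 0.28 log2 units, restates that the probe set was not higher and would be the same with the transgene absent. The labels give neither the species nor the part of OVOL2 in the virus, and 0 further probe sets name the gene. A virus that was silenced or absent in these cells was not tested.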

How the results depend on the processing

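The tests of mesenchymal genes without those shared with the fibroblast list were chosen after seeing the data (adjusted p = 4.59e-06, and 0.337 with an estimated correlation), and the other alternatives were planned. The count of 5196 changed genes (2471 higher, 2725 lower) lay within 1.5 times under most settings, from 4425 with the replicate block to 6771 at an adjusted p of 0.1. It fell to 2847 with the floor (1545 higher, 1302 lower), and to 1364 with at least a 2-fold difference (546 higher, 818 lower), as the stricter threshold requires. The floor lay no higher than 4.9, the highest lower quartile of the arrays. Bright genes such as Prrx1 kept their values there and still lost their call. For these the spread pooled over genes or the adjustment had changed. How much of the whole drop this explains was not tested. Without 1 array, the lone array of a group being assumed to vary like the other group, the count ran from 0 to 7383 (higher 0 to 3079, lower 0 to 4304). The 0 arose without either control array, where the spread came from the pair labelled OVOL2 alone, which differed more (SD of the difference 0.251 against 0.138), with 1 residual degree of freedom. The replicate numbers did not pair the samples (r = -0.04 across genes), and the block gave 4425 genes and 14 lists.

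Of 14 called lists, 0 were called by camera with an estimated correlation. Adjusted p-values were then 0.321 for the mesenchymal, fibroblast, G2 and M, interferon and oxidative phosphorylation lists, 0.337 for S phase and NF-kB, and 0.366 for keratins, cholesterol synthesis, FGF and EGF, and housekeeping. They were 0.47 for TGF-beta, 0.492 for astrocytes and 0.672 for Hedgehog. This setting rests on 2 residual degrees of freedom by construction. Fry called 15 lists, 3 of them not called by camera, with 0.0156 for epithelial junctions, 0.0159 for endothelial and mural cells and 0.0314 for immediate early genes. It gave 0.0515 for TGF-beta and 0.108 for Hedgehog. Housekeeping gave 0.0711 under quantile normalisation and 0.107 with the filter, FGF and EGF 0.136 with the filter, and EMT factors 0.0328 with the mean of probe sets. The cause was not tested. Without 1 array the adjusted p ran from 0.0149 to 0.0747 for FGF and EGF, 0.0277 to 0.0777 for housekeeping, 0.000366 to 0.121 for Hedgehog and 0.0355 to 0.144 for EMT factors. Of the named genes, 53 lost their call with the floor, 18 with every probe set on its own, 9 with the block, and 130 without either control array. Counts within lists moved by over 1.5 times for 25 of 32 lists with the floor, 10 with the block, 8 with the intensity trend and at most 4 with each other scaling, filter or summary. Rps24 reversed from -0.30 to 0.10 with the mean of its probe sets, which disagree in sign. The Ovol2 difference ran from -0.03 to 0.12 without 1 array and passed no threshold. Without signal over background, the limit for dim genes is unknown.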

Other observations

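Quantile normalisation was planned, and the other tests in this part, with the 5 gene lists tested together here, were chosen after the data were seen. The most even of them was a list of ribosome assembly factors, which build ribosomal subunits in the nucleolus. Of 33 measured genes 32 rose and none fell, with a median of 1.08 log2 units. Nop56, a core protein of small nucleolar ribonucleoproteins, rose from 9.31 ± 0.04 to 11.11 ± 0.02 (SD, n = 2 arrays), Dkc1 (dyskerin) rose by 1.69 and Heatr1 by 1.58. Npm1 had 11.85 and 11.95. Myc, a regulator of such genes from outside the rule for named genes, rose from 9.65 to 10.34. Whether it acted on them was not tested. Leaving out Ddx21, which had been noticed first, 31 of 32 rose. The hypothesis that these factors rose as a group may hold, with a camera p of 4.23e-23, but the adjusted p over the 5 lists was 0.0989 with an estimated correlation.

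A list of NRF2 targets, genes of the response to oxidants, had 11 of 17 genes higher and 2 lower, with a median of 0.63. Gclc, which makes glutathione precursors, rose by 1.55, Gsr (glutathione reductase) by 1.48, Srxn1 by 1.47 and Nqo1 by 1.31. Hmox1 (heme oxygenase) and Ephx1 went the other way, at -1.24 and -0.73. Values of none of the 17 had been seen when the list was written, but the list was prompted by other genes of these arrays. That the targets rose as a group may hold only as a hypothesis, with a camera p of 5.96e-06 that describes these arrays, and 0.0989 after adjustment with an estimated correlation. The remaining lists were tested by camera with the genes seen before left out. In complement and acute phase genes 8 of 16 fell, with Cp (ceruloplasmin) at -1.94. Of the 15 tested 7 fell, and the limma camera adjusted p over the 5 lists was 8.25e-05. Of 14 small leucine-rich proteoglycans 6 fell, but only 1 of the 6 tested, with a median of -0.23 and a limma camera adjusted p of 0.122. Of 10 bone and mineralisation genes 4 fell, 1 of them among the 6 tested, with a limma camera adjusted p of 0.351. With an estimated correlation the adjusted p of these lists was 0.278, 0.289 and 0.44.

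Of 49 measured mesenchymal genes 31 fell, 6 rose and 12 did not pass the test on the arrays labelled OVOL2. Normalisation between arrays that moves genes of one level alike is argued against as the whole cause of these falls. The 31 genes that fell had a median of -1.41, which is large partly because they were picked for falling, and all 49 had -1.07. The 50 genes nearest in control mean to each of the 31, outside the mesenchymal and fibroblast lists, had a median of -0.08. Lists drawn with 1 such gene per member had 95% of their medians between -0.33 and 0.10, and the lowest was -0.67. Fewer cells of a fibroblast type may account for part of the fall. Of 14 fibroblast genes above the control upper quartile, a bound set after seeing the data, 8 lay over 1 log2 unit from their median of -1.90, with a range from -3.37 to 1.60. This cannot be told apart from regulation within cells, because other cells of the culture could make the genes that stayed.

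Among 851 genes with a mean fall of at least 1 log2 unit, 82.1% were lower on array 2 labelled OVOL2 than on array 1. The mean that picked these genes includes array 2, which correlated less with the controls than array 1 did. How far this choice adds to the share was not tested. Array scaling as the whole cause is argued against, since 78.5% were lower after quantile normalisation. A larger share of responding cells in the sample of array 2, which the labels do not describe as a separate culture, might also carry the 564 risen genes farther out. Of these 52.5% were farther out on array 2, with a 95% exact binomial interval of 48.3 to 56.7 that treats genes as independent, and 65.8% after quantile normalisation. The values do not decide between these readings.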
